A study of Mus musculus with 8 samples.

How the data were processed

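Gene-level read counts were compared between 2 groups of 4 RNA-seq libraries from mouse peripheral retina at postnatal day 12. Per the labels, the tissue was microdissected, RNA was extracted with Trizol, and libraries were made from oligo-dT selected RNA with a NEBNext Ultra kit. All 8 libraries were assigned to their groups from the genotype given in the labels. The labels do not state that each library came from a separate animal, so p-values measure the spread between these libraries, which may be partly technical. No batch or date is given there.

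The authors deposited 1 table of whole-number counts per gene symbol for each library, without normalization. Per the submitters' processing notes, the tools named were CASAVA 1.8.2, TopHat2 2.0.8b and HTSeq 0.5.4p3, with the mouse build mm9. Their options, the annotation and the use of strand are not given in the sources used here, so reads of a gene and of an overlapping or antisense partner cannot be told apart. The supplied annotation is of another build (GRCm38), so no coordinates are given, and it served only for transcript lengths. Reads that HTSeq placed in no gene, in several genes or at several genomic places were kept out of library sizes and tests. They made up 28.3% to 31.7% of the reads in each file, and those without a gene alone made up 15.1% to 19.7%. Reads aligned to several places were 9.05% to 12.8%, so genes with near-identical copies, such as ribosomal protein genes with processed pseudogenes, metallothioneins and gamma crystallins, are uncertain.

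Counts were scaled by TMM, and filterByExpr with the group kept 15106 of 23284 genes. The test was edgeR's quasi-likelihood F test (edgeR 4.0.16, estimateDisp, glmQLFit with robust = TRUE, glmQLFTest; R 4.3.3), with an intercept and the group and no covariate, and Benjamini-Hochberg adjustment at 0.05. A positive log2 fold change means higher in the libraries labelled TET-MYCN. The ± after a log2 fold change is its standard error, computed as its absolute value over the square root of F, and the ± after CPM is the SD over 4 libraries. CPM used TMM-scaled library sizes. A count of 3 corresponded to 0.131 to 0.202 CPM, depending on the library, and floors and counting intervals cover counting error only.

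The 33 gene lists, the rule for named genes and the other settings were fixed before the data were examined. The rule took Mycn, Rb1, Myc, Mycl (Mycl1 in the files) and Max, then up to 10 genes per direction past the threshold with a mean CPM of at least 5 and groups that did not overlap, and then the 4 members with the smallest unadjusted p in each list. Members were to be named for lists past the threshold, and 2 of those the rule takes are not reported here. The 32 lists with at least 5 tested genes were tested with limma's camera (limma 3.58.1) on log2 CPM with a prior count of 2, a preset inter-gene correlation of 0.01 and Benjamini-Hochberg adjustment over the lists. Camera compares a list with all other genes tested. Alternatives fixed beforehand were camera with a correlation estimated per list and fry. An exact permutation test of each list's mean log2 CPM per library was added after seeing the data.

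Other settings fixed beforehand for gene counts were DESeq2's size factors, total counts alone, no filter on low counts, a filter of at least 1 CPM in at least 4 libraries, DESeq2 1.42.0, limma-voom, the replicate number as a block, and each library left out in turn. Alternatives added after seeing the data were edgeR's newer quasi-likelihood method, a Y-linked score as a covariate, the exact permutation test of list means, and fits without the pair of libraries richest in crystallin reads or the pair with the most multiply aligned reads. The package's default quasi-likelihood setting was kept for the main test after both settings had been run, and both called 9 genes. Single values per library were compared by two-sided exact permutation tests over all 70 arrangements of the 8 libraries. No pair of libraries of a group agreed within sampling noise. Figures were drawn with Python 3.11.15 and matplotlib 3.10.9.

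The procedure was tested on simulated counts for the comparison of the 2 groups, drawn from the libraries' means and sizes, with known changes. In 15006 simulated genes edgeR recovered 74 of 100 genes changed 2-fold and 97 of 100 changed 4-fold, with 11 false calls. DESeq2, on 15106 simulated genes, recovered 85 and 100, with 26 false calls. On the 15006 genes limma-voom recovered 71 and 96, with 10 false calls. Each gene was drawn independently, so the simulation held no variation shared by genes across libraries. Its recovery and false calls need not carry over to the real counts, where edgeR, DESeq2 and limma-voom called 9, 536 and 0 genes.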

Results

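RNA was sequenced from the peripheral retina of mice at postnatal day 12, where the alpha enhancer of Pax6 drives Cre recombinase. In 4 libraries the tissue was Rb-null through deletion of floxed Rb1, the retinoblastoma tumour suppressor gene. In the other 4, labelled TET-MYCN, the labels add a tetracycline-regulated MYCN transgene and a Cre-dependent transactivator. The comparison asks which transcripts differ when MYCN is overexpressed in Rb-null retina. The series text does not repeat the floxed Rb1 allele for the second group, whereas the genotype label calls it Rb-null, and no doxycycline treatment is stated in the labels used here. Gene counts were 20007977, 16101383, 15555765 and 14872131 in Rb-null libraries 1 to 4, and 16166000, 22873979, 17861514 and 19773139 in TET-MYCN libraries 1 to 4.

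Mouse Mycn had 231 ± 95.0 CPM in the Rb-null libraries and 242 ± 37.6 CPM in those labelled TET-MYCN (n = 4 each), a log2 fold change of 0.07 ± 0.28 (adjusted p = 0.934, edgeR's quasi-likelihood test). Its level was 246, 339, 108 and 232 CPM in Rb-null libraries 1 to 4, and 201, 219, 272 and 276 CPM in the TET-MYCN libraries. Rb1 had 161 ± 21.9 and 154 ± 23.6 CPM, a log2 fold change of -0.06 ± 0.14 (adjusted p = 0.883). Its level was 184, 174, 147 and 138 CPM in Rb-null libraries 1 to 4, and 151, 179, 164 and 123 CPM in the TET-MYCN libraries. The log2 fold changes were -0.32 ± 0.37 for Myc, 0.58 ± 0.28 for Mycl1 and -0.19 ± 0.15 for Max, the dimerization partner of MYC proteins, with adjusted p of 0.731, 0.346 and 0.581. These genes check the labels little, since transgene reads need not be counted at the mouse Mycn gene, a floxed Rb1 allele can leave most exons in place, and the tissue may hold cells without Cre. Direction below therefore rests on the labels. The small values of Mycn and Rb1 changed sign without 1 library, Mycn to -0.17 without Rb-null 3, and Rb1 to 0.014 without Rb-null 1 and 0.036 without TET-MYCN 4.

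Of 15106 genes tested, 9 differed between the groups, 8 higher and 1 lower in the libraries labelled TET-MYCN, and 8 by over 2-fold. Mmp12, the macrophage metalloelastase, had 10 counts in all 4 Rb-null libraries together (2 to 3 per library) and 1091 in the TET-MYCN libraries, a ratio, scaled to the gene counts, of 94.7 with a 95% counting interval of 51.3 to 198.0 (exact binomial). It stood at 20.5, 1.73, 13.0 and 24.6 CPM in TET-MYCN libraries 1 to 4 and 0.151 ± 0.0328 CPM in the Rb-null libraries. Pnoc, the precursor of the neuropeptide nociceptin, rose from 1.13 ± 0.226 to 9.11 ± 4.41 CPM (log2 fold change 3.01 ± 0.37). Ndufa4l2, a hypoxia-induced mitochondrial protein gene, rose from 15.4 ± 4.16 to 81.2 ± 22.9 CPM (2.39 ± 0.25).

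Slc10a4, a vesicular transporter of the bile acid transporter family, rose from 1.79 ± 0.329 to 8.93 ± 2.90 CPM (log2 fold change 2.32 ± 0.29, n = 4 each). The potassium channel gene Kcnk2 rose from 3.31 ± 0.554 to 15.2 ± 4.37 CPM (2.20 ± 0.25). The long non-coding RNA Sox2ot rose from 10.9 ± 2.61 to 44.7 ± 14.3 CPM (2.03 ± 0.26). Sox2 lies within the Sox2ot locus, so reads of the pair may not be fully separated, and Sox2 itself, named for this overlap after its values were seen, had a log2 fold change of 0.59 ± 0.18 (adjusted p = 0.194). The non-coding RNA E130218I03Rik fell from 89.8 ± 10.5 to 46.0 ± 5.91 CPM (-0.96 ± 0.12). Fezf1, a zinc-finger transcription factor of the developing forebrain, and the orphan receptor gene Gpr52 also rose. They were under the mean level of the naming rule and are named after their values were seen, at 0.335 ± 0.0470 to 4.18 ± 1.85 CPM for Fezf1 (3.62 ± 0.42) and 0.425 ± 0.141 to 2.52 ± 0.748 CPM for Gpr52 (2.53 ± 0.33). The groups of 4 did not overlap for any of the 9 genes, whose adjusted p lay between 0.0301 and 0.0348 (edgeR's quasi-likelihood test, Benjamini-Hochberg). Over all genes tested, 1156 (7.65%) had groups that did not overlap, against 2.86% by chance, and 2384 had an unadjusted p under 0.05, against 755.3 expected. Genes vary together across libraries, so neither excess alone shows a group effect. Other divisions of the libraries into 4 and 4 gave 38 to 3381 genes at an unadjusted p under 0.05. At an adjusted p under 0.1, 36 genes passed. The count varied with the tool, from 0 with limma-voom (2262 at an unadjusted p under 0.05) to 536 with DESeq2, which called all 9. It fell to 1 without Rb-null 1 and to 0 without any 1 of Rb-null 2, 3 and 4 and TET-MYCN 1 and 4, and became 132 without TET-MYCN 2 and 230 without TET-MYCN 3.

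**Figure D1:**
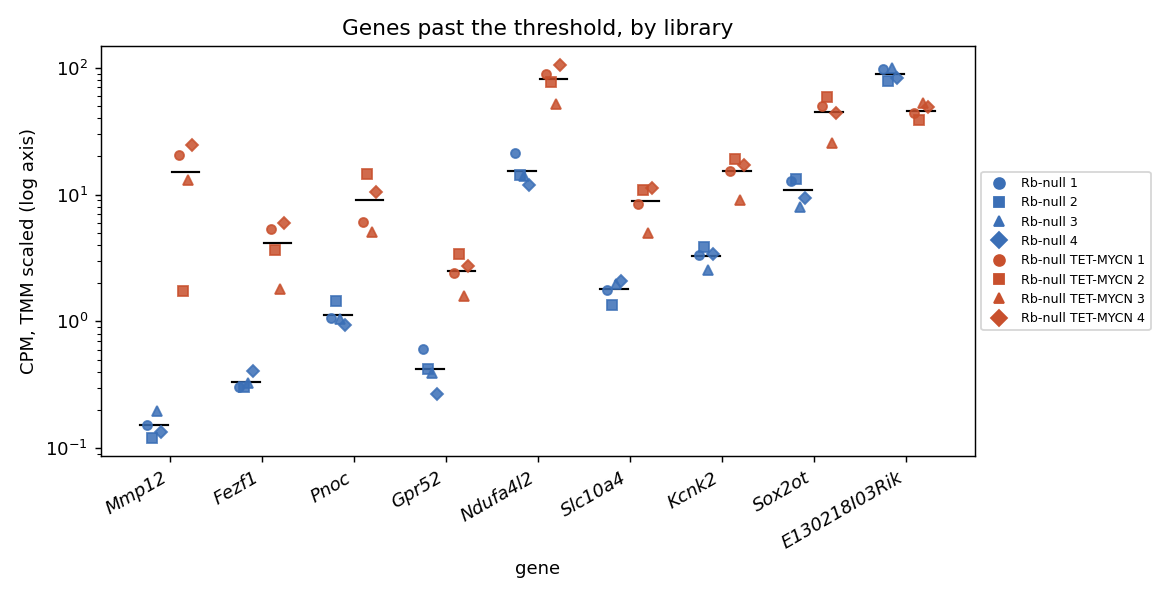
CPM of the 9 genes that differed between the groups, on a log axis, with 1 point per library (blue, Rb-null; orange, TET-MYCN; the shape gives the library's number) and a line at each mean of 4. The groups do not overlap for any of these genes, and Mmp12 in TET-MYCN 2, at 1.73 CPM, is the lowest of its group.

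Genes of ribosomes and protein synthesis were higher as lists in the libraries labelled TET-MYCN when tested with camera's preset correlation. All 41 cytosolic ribosomal protein genes had a positive log2 fold change, with a median of 0.53 (adjusted p = 1.04e-22, camera; adjusted p = 0.495 with an estimated correlation). Over all genes tested 0 members passed, and adjusted over the list alone 39 passed as higher and 0 as lower. Log2 fold changes were 0.70 ± 0.15 for Rps20, 0.69 ± 0.15 for Rps4x and 0.59 ± 0.14 for Rplp2. TET-MYCN 2 stood apart from its group for these genes, for example at 380.2 CPM of Rps4x against 578, 552 and 629 CPM in the other 3. In ribosome biogenesis and the nucleolus, 36 of 40 genes were positive, with a median of 0.24 (adjusted p = 9.07e-08, camera; adjusted p = 0.495 with an estimated correlation). Adjusted over the list alone, 1 member passed as higher and 0 as lower, and over all genes tested 0 passed. Leading members had log2 fold changes of 0.49 ± 0.11 for Gar1, 0.59 ± 0.16 for Nhp2, 0.53 ± 0.15 for Npm1 and 0.54 ± 0.16 for Fbl. These members code for nucleolar proteins. In nucleotide and polyamine synthesis, 25 of 26 genes were positive, with a median of 0.30 (adjusted p = 1.25e-07, camera; adjusted p = 0.495 with an estimated correlation). In this list 8 members passed as higher and 1 as lower when adjusted over the list alone, and 0 over all genes tested. Among its members, log2 fold changes were 0.59 ± 0.16 for Atic, 0.38 ± 0.11 for Umps and 0.48 ± 0.15 for Nme1. Phgdh, which opens serine synthesis, was at 18.0 ± 2.95 and 36.0 ± 12.5 CPM. Translation factors and tRNA synthetases had a median of 0.19, 23 of 27 positive (adjusted p = 1.93e-04, camera; adjusted p = 0.495 with an estimated correlation). No member passed, with 0 over all genes tested and 0 adjusted over the list alone. The smallest p-values went with log2 fold changes of 0.66 ± 0.19 for Eif4ebp1, 0.42 ± 0.12 for Eif5a, 0.36 ± 0.13 for Eif3b and 0.27 ± 0.10 for Dars. Mitochondrial ribosome and import genes had a median of 0.16, 25 of 26 positive (adjusted p = 6.29e-04, camera; adjusted p = 0.531 with an estimated correlation). Over all genes tested 0 members passed, and adjusted over the list alone 1 passed as higher and 0 as lower. Log2 fold changes were 0.47 ± 0.11 for C1qbp, 0.40 ± 0.11 for Hspd1, 0.51 ± 0.16 for Timm8a1 and 0.42 ± 0.14 for Hspe1. Its call was lost without TET-MYCN 3 (median 0.08, 17 of 26 positive, adjusted p = 0.153) and, in a fit chosen after seeing the data, without Rb-null 1 and TET-MYCN 3, which had the most multiply aligned reads (adjusted p = 0.274).

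Genes of the cell cycle and of retinal progenitors were also higher as lists by the same test. All 40 mitosis genes were positive, with a median log2 fold change of 0.42 (adjusted p = 1.91e-13, camera; adjusted p = 0.495 with an estimated correlation). Adjusted over the list alone, 5 members passed as higher and 0 as lower, and over all genes tested 0 passed. Leading members had log2 fold changes of 0.72 ± 0.15 for Ube2c, 0.69 ± 0.16 for Cdc25c, 0.86 ± 0.21 for Cenpa and 0.73 ± 0.20 for Cdc20. Without Rb-null 3 the list's median was 0.28 (adjusted p = 1.61e-11, camera). DNA replication genes had a median of 0.22, 38 of 39 positive (adjusted p = 5.91e-06, camera; adjusted p = 0.531 with an estimated correlation). No member passed, with 0 over all genes tested and 0 adjusted over the list alone. Among its members, log2 fold changes were 0.43 ± 0.16 for Chaf1b, 0.34 ± 0.13 for Rfc5, 0.58 ± 0.23 for Tk1 and 0.40 ± 0.16 for Mcm6. Without Rb-null 3 the median was 0.12, with 30 of 39 positive (adjusted p = 0.00947). The list's mean log2 CPM was 6.68 and 6.82 in Rb-null 1 and 2, above 6.61 and 6.65 in TET-MYCN 1 and 2. Rb-null 3 and 4 had 6.10 and 6.49, and TET-MYCN 3 and 4 had 6.92 and 6.85. Chromatin and DNA repair genes of S phase had a median of 0.25, 21 of 24 positive (adjusted p = 6.29e-04, camera; adjusted p = 0.531 with an estimated correlation). No member passed, with 0 over all genes tested and 0 adjusted over the list alone. The smallest p-values went with log2 fold changes of 0.30 ± 0.10 for Msh6, 0.43 ± 0.20 for Exo1, 0.36 ± 0.18 for Fanci and 0.38 ± 0.19 for Smc2. Without Rb-null 3 the median was 0.12, with 19 of 24 positive (adjusted p = 0.0442). This list's mean log2 CPM was highest of all libraries in Rb-null 2, at 6.61, against 6.46 to 6.57 in the TET-MYCN libraries. Rb-null 1, 3 and 4 had 6.49, 5.88 and 6.14. Among retinal progenitor genes 25 of 27 were positive, with a median of 0.52 (adjusted p = 6.71e-08, camera; adjusted p = 0.495 with an estimated correlation). Over all genes tested 0 members passed, and adjusted over the list alone 10 passed as higher and 1 as lower. Log2 fold changes were 1.28 ± 0.19 for Hmga2, 2.70 ± 0.57 for Atoh7, 2.54 ± 0.55 for Igf2bp1 and 1.08 ± 0.28 for Lin28b. Hmga2, a chromatin protein of early progenitors, was at 3.90 ± 0.593 and 9.47 ± 1.68 CPM (adjusted p = 0.0587), and Atoh7, which is needed for ganglion cell fate, was at 0.953 ± 0.329 and 6.27 ± 5.67 CPM, with 14.8 CPM in TET-MYCN 4.

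Genes of rods, cones, bipolar cells, ganglion cells and synapses were lower as lists by the same test, while the horizontal and amacrine cell lists did not pass (adjusted p = 0.696 and 0.655). All 26 rod photoreceptor genes had a negative log2 fold change, with a median of -1.01 (adjusted p = 3.51e-08, camera; adjusted p = 0.495 with an estimated correlation). Adjusted over the list alone, 0 members passed as higher and 1 as lower, and over all genes tested 0 passed. Leading members had log2 fold changes of -1.78 ± 0.40 for Pde6b, -1.23 ± 0.43 for Sag, -1.08 ± 0.38 for Reep6 and -1.10 ± 0.40 for Prph2. Rod transcripts varied within the groups, as shown by Pde6b, the rod phosphodiesterase subunit, at 219 to 843 CPM in the Rb-null libraries and 80.3 to 199 CPM in the TET-MYCN libraries. Cone genes had a median of -0.75, 13 of 14 negative (adjusted p = 4.80e-04, camera; adjusted p = 0.495 with an estimated correlation). No member passed, with 0 over all genes tested and 0 adjusted over the list alone. Among its members, log2 fold changes were -1.14 ± 0.44 for Kcne2, -0.50 ± 0.20 for Gnb3 and -0.59 ± 0.27 for Thrb. Without Rb-null 3 the median was -0.37 (adjusted p = 0.00808). Arr3, the cone arrestin, was at 72.5 ± 26.7 and 36.2 ± 13.7 CPM. Bipolar cell genes had a median of -0.69, 21 of 22 negative (adjusted p = 8.29e-08, camera; adjusted p = 0.495 with an estimated correlation). With adjustment over all genes tested 0 members passed, while adjusted over the list alone 0 passed as higher and 11 as lower. The smallest p-values went with log2 fold changes of -0.99 ± 0.22 for Gpr179, -1.42 ± 0.36 for Grm6 and -1.38 ± 0.36 for Pcp2. Grm6 is the glutamate receptor of ON bipolar cells. Ganglion cell genes had a median of -0.46, 15 of 21 negative (adjusted p = 0.00522, camera; adjusted p = 0.495 with an estimated correlation). Over all genes tested 0 members passed, and adjusted over the list alone 0 passed as higher and 1 as lower. Log2 fold changes were -0.87 ± 0.20 for Nefh, 0.53 ± 0.15 for Gap43, -1.15 ± 0.35 for Pou4f3 and -0.80 ± 0.26 for Chrna6. Leaving out Rb-null 4 gave a median of -0.29 (adjusted p = 0.0207). Over all 8 libraries Gap43, a growth cone protein, had a positive value. Synapse and neuronal maturation genes had a median of -0.43, 29 of 33 negative (adjusted p = 6.17e-07, camera; adjusted p = 0.495 with an estimated correlation). Adjusted over the list alone, 1 member passed as higher and 12 as lower, and over all genes tested 0 passed. Leading members had log2 fold changes of -0.50 ± 0.13 for Sv2a, -0.68 ± 0.18 for Camk2a, -1.39 ± 0.43 for Gabrr1 and -1.11 ± 0.34 for Cacna2d4.

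In the list of Müller glia and astrocytes, members went both ways. Of 21 genes 13 were negative, with a median log2 fold change of -0.35 (adjusted p = 0.0229, camera; adjusted p = 0.495 with an estimated correlation). In this list 3 members passed as higher and 6 as lower when adjusted over the list alone, and 0 over all genes tested. Among its members, log2 fold changes were -0.97 ± 0.15 for Kcnj10, -1.08 ± 0.19 for Aqp4, -1.26 ± 0.25 for Glul and 1.17 ± 0.23 for Hes5. Kcnj10 and Aqp4, the potassium and water channels of mature Müller glia, were at 56.0 ± 7.74 and 81.6 ± 9.33 CPM in the Rb-null libraries and 28.5 ± 4.89 and 38.5 ± 10.8 CPM in the TET-MYCN libraries (adjusted p = 0.0632 and 0.0931). Hes5, a Notch target of progenitors and immature glia, was at 30.4 ± 9.55 and 68.5 ± 16.3 CPM (adjusted p = 0.135). The list's call was lost without Rb-null 2 (median -0.19, adjusted p = 0.137), without TET-MYCN 1 (median -0.18, adjusted p = 0.119), and without the crystallin-rich libraries Rb-null 2 and 3 (0.0672), the last chosen after seeing the data. It held without TET-MYCN 4, with a median of -0.20 (adjusted p = 0.0207).

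Stress genes of photoreceptors and glia were higher as a list, 17 of 20 positive, with a median log2 fold change of 0.47 (adjusted p = 7.52e-05, camera; adjusted p = 0.495 with an estimated correlation). With adjustment over all genes tested 0 members passed, while adjusted over the list alone 5 passed as higher and 0 as lower. The smallest p-values went with log2 fold changes of 1.25 ± 0.18 for Mt2, 0.91 ± 0.16 for Mt1 and 5.46 ± 1.12 for Lcn2. C3, the central complement component, was at 1.28 ± 0.376 and 4.51 ± 2.83 CPM. The metallothionein gene Mt2 was at 12.2 ± 1.57 and 28.8 ± 6.18 CPM (adjusted p = 0.0543). Lcn2, the iron-carrier binding protein lipocalin-2, was at 46.1, 36.1 and 23.7 CPM in TET-MYCN 1, 3 and 4 but 0.346 CPM in TET-MYCN 2, within the Rb-null range of 0.182 to 0.875 CPM. Ciliary margin, iris and pigment epithelium genes had a median of 0.54, 16 of 21 positive (adjusted p = 0.00146, camera; adjusted p = 0.495 with an estimated correlation). Over all genes tested 0 members passed, and adjusted over the list alone 6 passed as higher and 0 as lower. Log2 fold changes were 2.95 ± 0.57 for Bmp4, 2.17 ± 0.50 for Gja1, 2.78 ± 0.71 for Otx1 and 1.74 ± 0.46 for Zic1. Leaving out TET-MYCN 4 gave a median of 0.20 (adjusted p = 0.0348). Gja1, which codes for connexin 43, was at 79.1 and 90.6 CPM in TET-MYCN 1 and 4 and 14.4 CPM in TET-MYCN 2, against 10.4 to 13.7 CPM in the Rb-null libraries. Lens genes had a median of -3.29, 18 of 19 negative (adjusted p = 9.01e-10, camera; adjusted p = 0.495 with an estimated correlation). Adjusted over the list alone, 0 members passed as higher and 15 as lower, and over all genes tested 0 passed. Leading members had log2 fold changes of -2.58 ± 0.62 for Crybb3, -1.82 ± 0.45 for Lgsn, -3.24 ± 0.80 for Cryba4 and -3.15 ± 0.81 for Crybb1. Crystallin reads summed to 61.5, 415, 801 and 178 CPM in Rb-null 1 to 4 and 85.8, 62.4, 104 and 33.8 CPM in TET-MYCN 1 to 4 (exact permutation p = 0.114, two-sided). Without the crystallin-rich Rb-null 2 and 3, a fit chosen after seeing the data, edgeR called 0 genes (1306 at an unadjusted p under 0.05; other tools were not run without them). The log2 fold changes of the 9 genes were then 95.2% to 105% of those over all 8 libraries, with standard errors 1.24 to 1.48 times as large and adjusted p of 0.484 to 0.528. Ndufa4l2 had 2.28 ± 0.34 against 2.39 ± 0.25.

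Of the 32 lists tested, camera with the preset correlation thus called 18, of which 11 were higher and 7 lower. With an estimated correlation it called 0 (smallest unadjusted p = 0.0734), and fry called 0 for direction (smallest adjusted p = 0.187). For change either way fry called 5. These were Müller glia and astrocytes and endothelium, pericytes and fibroblasts (adjusted p = 0.0218 each, fry), and translation factors, retinal progenitors and stress genes (0.0395 each). Camera did not call the endothelium list. An exact permutation test of the list means per library, chosen after seeing the data, called 0 (smallest adjusted p = 0.261). That adjusted count says little alone, since the smallest p of 8 libraries is 0.0286. At that value 19 of the 32 lists would be needed for any to pass after adjustment. Unadjusted, the exact permutation p was 0.0286 for nucleotide and polyamine synthesis and for translation factors. For the other lists that camera called it was 0.0571 to 0.286, so none of those was under 0.05 at the level of libraries. Rb-null 3 had the lowest mean of the 8 libraries in 8 of the 11 lists called higher, among them those of the cell cycle, retinal progenitors and cytosolic ribosomal proteins, and the highest in 5 of the 7 called lower, among them rods, cones and bipolar cells. The means per library did not overlap between the groups for 2 lists, nucleotide and polyamine synthesis and translation factors. This restates their permutation p of 0.0286 and is not a second result. The gaps were small, 6.29 in TET-MYCN 2 against 6.28 in Rb-null 2 for nucleotide and polyamine synthesis. For translation factors they were 6.87 in TET-MYCN 2 against 6.84 in Rb-null 4. Other divisions of the 8 libraries gave 18 or more calls as well, up to 21, so the number of lists called does not set the labelled groups apart.

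**Figure D2:**
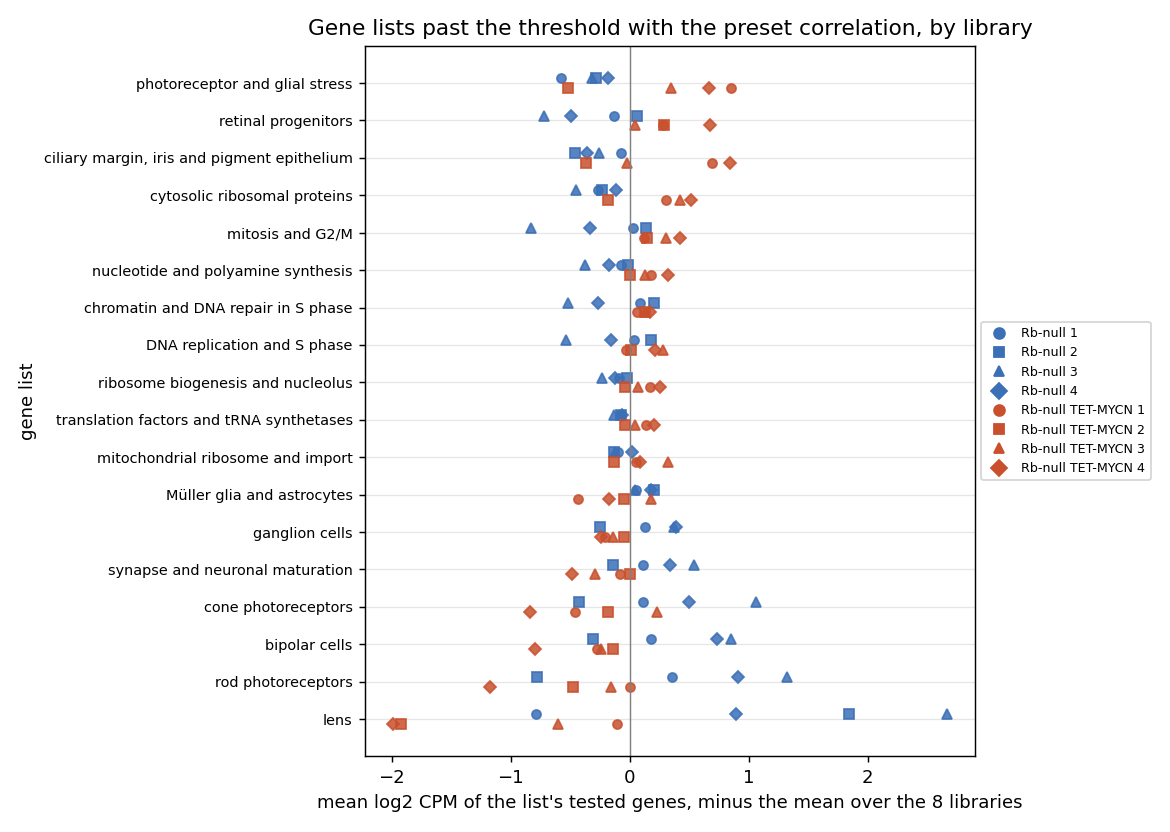
Mean log2 CPM of each of the 18 lists past the threshold with the preset correlation, centred on the mean of the 8 libraries, with 1 point per library (blue, Rb-null; orange, TET-MYCN; the shape gives the library's number). The groups overlap for all lists but nucleotide and polyamine synthesis and translation factors, and TET-MYCN 2 lies beside the Rb-null libraries for ribosomal protein and stress genes.

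The other 14 lists did not pass with the preset correlation, and 0 of their members passed over all genes tested. Among regulators, the MYC family had a median log2 fold change of 0.04 over 11 genes (adjusted p = 0.875, camera) and the RB family and E2F genes 0.12 over 13 (adjusted p = 0.139). Medians were 0.10 for p53 targets and apoptosis, 0.04 for the respiratory chain, 0.08 for glycolysis and lactate, 0.11 for polyadenylated histones and -0.08 for immediate early genes, with adjusted p of 0.159, 0.875, 0.655, 0.655 and 0.874. Among cell types, medians were -0.15 for photoreceptor precursors, 0.64 for horizontal cells, -0.08 for amacrine cells, 0.14 for microglia and macrophages and -0.23 for endothelium, pericytes and fibroblasts, with adjusted p of 0.159, 0.696, 0.655, 0.103 and 0.151. The amacrine mean was 0.05, of the opposite sign to its median. The interferon list had -0.32 and the sex-linked list -0.69 (adjusted p = 0.370 and 0.206). Adjusted over the list alone, 2 horizontal cell genes passed as higher and 2 as lower, 2 microglia and macrophage genes and 1 interferon gene passed as higher, and 0 passed in the other 11 of these lists. The red blood cell list had 1 tested gene and was not tested as a set.

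Xist, transcribed from the inactive X chromosome, and 4 Y-linked genes (Ddx3y, Eif2s3y, Kdm5d and Uty) were compared library by library. Rb-null 3 and TET-MYCN 2 and 4 had 2537, 3688 and 3049 CPM of Xist and a Y-linked sum of 0.393, 0.173 and 0.302 CPM. TET-MYCN 1 had 9.76 CPM of Xist and 218 CPM of Y-linked reads. The remaining 4 libraries held both, with 1702, 2876 and 584 CPM of Xist in Rb-null 1, 2 and 4 and 503 CPM in TET-MYCN 3, and Y-linked sums of 241, 215, 157 and 149 CPM. With the Y-linked score as a covariate, chosen after seeing the data, edgeR called 0 genes (2433 at an unadjusted p under 0.05; other tools were not run with it). The log2 fold changes of the 9 genes were 88.9% to 101% of those without the covariate, with standard errors 0.873 to 1.13 times as large, fewer residual degrees of freedom and adjusted p of 0.0846 to 0.116. Slc10a4 had 2.13 ± 0.26 against 2.32 ± 0.29.

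**Figure D3:**
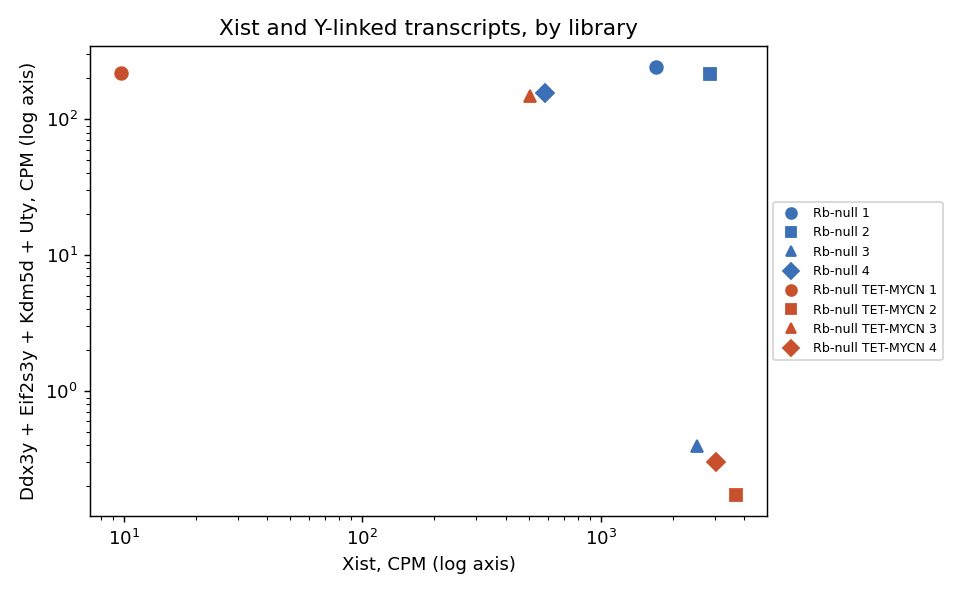
Xist against the sum of 4 Y-linked genes (Ddx3y, Eif2s3y, Kdm5d and Uty) in CPM, both on log axes, with 1 point per library (blue, Rb-null; orange, TET-MYCN; the shape gives the library's number). Rb-null 1, 2 and 4 and TET-MYCN 3 have over 100 CPM on both axes.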

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

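The tests of leaving out libraries and of the slope on multiply aligned reads, of the rod score as a covariate, and both tests of Xist with Y-linked reads were chosen after the result, or the values they rest on, had been seen. The requirement that a value clear its bound by more than its standard error was also applied after these values were seen, and it left the rod tests of ribosomal and progenitor genes open where they had been read as decided. A rod test on Glul, Aqp4 and Kcnj10, which had been picked for their low values, was replaced by one on the whole Müller glia and astrocyte list.

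In 8 of 180 groups of 4 libraries 1 library stood far from the other 3, which is 4.44%, while chance gives about 1 in 20 groups. All 8 were in the TET-MYCN group, so the pooled share hides a difference between the groups. Most of the values tested were of genes named for small p, and genes vary together, so the chance rate is only a rough guide. Mycl1 was 83.2 CPM in TET-MYCN 4 against 51.9 to 56.5 in the other 3, Hes5 was 92.9 CPM against 58.8 to 61.2, and Atoh7 was 14.8 CPM against 3.09 to 3.85. Gabrr1, a retinal GABA receptor subunit gene, was 5.59 CPM in the same library against 13.2 to 14.2. In TET-MYCN 2, Nhp2 was 26.4 CPM against 39.3 to 40.8 and Cdc25c was 18.1 CPM against 24.1 to 24.7. In TET-MYCN 3, Glul was 1074 CPM against 610 to 659, and 12.8% of reads were aligned to several places against 9.15% to 9.73%.

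The number of genes that differed was set against all 35 divisions of the 8 libraries into 4 and 4. The labelled division gave 9 genes, the highest other gave 1, and 1 of the 35, the labelled one itself, gave as many. That is the smallest share 35 divisions can reach, so the labelled division stands out but chance is not excluded. The same held for genes over 2-fold (8 against 1, 1 of 35) and for the larger direction (8 against 1, 1 of 35). Both are counts among the same 9 genes, so they add no separate support. For gene lists called by camera, 12 of the 35 divisions gave as many as the 18 of the labelled one, the highest other gave 21, and chance cannot be excluded. The division that set Rb-null 1, 3 and 4 with TET-MYCN 3 against the rest had 3381 genes at an unadjusted p under 0.05, above the 2384 of the labelled one, though it had 1 gene past the adjusted threshold.

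In the Müller glia and astrocyte list 13 of 21 genes were negative (adjusted p = 0.0229, camera; adjusted p = 0.495 with an estimated correlation) and in the retinal progenitor list 25 of 27 were positive (adjusted p = 6.71e-08, camera; adjusted p = 0.495 with an estimated correlation), and a lower share of photoreceptor-rich tissue was weighed as a source of both. With the rod score of each library as a covariate, the group coefficient of the Müller glia and astrocyte list was -0.28 ± 0.18 (SE) against -0.24 ± 0.13 without it, which is within 2 standard errors of 0 and decides nothing for a list whose members went both ways. For retinal progenitor genes it was 0.29 ± 0.11 against 0.65 ± 0.22, so the rod share cannot be told apart from the group here, since 8 libraries leave the value within its error of the bound. The rod score is itself lower in the TET-MYCN group, and a delay or loss of photoreceptors could give the same values as dissection. The labelled genotype stays open as an untested biological source.

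All 41 cytosolic ribosomal protein genes had a positive log2 fold change (adjusted p = 1.04e-22, camera; adjusted p = 0.495 with an estimated correlation; 0 members past the threshold over all genes), which was set against transcript length, multiply aligned reads and the rod share. The list median exceeded that of 10000 draws of genes of matched length by 0.47, and the draws ran from -0.12 to 0.25, which argues against length. Leaving out the pair of libraries with the most multiply aligned reads left a list difference of 0.48 ± 0.23 against 0.53, which decided nothing, and a further test was then chosen, in which the slope on that share gave a difference of 0.0111 ± 0.0128, which argues against a linear effect of that share as the source. With the rod score as a covariate the coefficient was 0.47 ± 0.22 against 0.53 ± 0.17, within its error of the bound, so the rod share cannot be told apart from the group for these genes. The genotype may play a part, but the number of lists called does not exceed chance divisions of the libraries.

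Xist and Y-linked reads occurred together in 4 libraries, and carry-over from another library and pooled tissue of both sexes were weighed. The smaller of the Xist and Y-linked shares, relative to the libraries with Xist or Y-linked reads alone, was 16.3% or more in each of the 4, above the bound of 10% set for carry-over. Tissue pooled from both sexes is a candidate source, and then the Xist and Y-linked ratios should sum to about 1. They summed to 0.908 and 0.844 in Rb-null 4 and TET-MYCN 3, but to 1.66 and 1.92 in Rb-null 1 and 2. With the highest Xist level as reference, Rb-null 1 and 2 had 1.57 and 1.76. These 2 libraries lie above what pooling alone would give, if the 1 library of Y-linked type is a fair reference. Its spread is unknown, so pooling cannot be told apart from other sources in the 4 libraries. No biological explanation was tested.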

How the results depend on the processing

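The fits with edgeR's newer quasi-likelihood method, the Y-linked covariate and either pair of libraries left out, and the permutation of list means, were chosen after seeing the data. The 9 genes kept their direction in all 19 alternatives. That says little, since they were picked in these same libraries and their groups did not overlap. Their adjusted p ranged from 9.88e-18 (DESeq2) to 0.528. The count of genes was 9 with DESeq2's size factors, 10 with total counts, 9 with the stricter filter and 9 with the newer method. Without a filter it was 17 (14 higher, 3 lower, 15 over 2-fold). DESeq2 called 536 (335 higher, 201 lower, 230 over 2-fold), of which edgeR tested 517, all of the same sign and at an unadjusted p under 0.05. Limma-voom called 0 (0 higher, 0 lower, 0 over 2-fold), with 2262 at an unadjusted p under 0.05. Leaving out 1 library gave 0 to 230 genes (0 to 176 higher, 0 to 54 lower, 0 to 140 over 2-fold). The count was 132 without TET-MYCN 2, 230 without TET-MYCN 3, 1 without Rb-null 1 and 0 without Rb-null 2, 3 or 4 or TET-MYCN 1 or 4, where 1391 to 2739 genes had an unadjusted p under 0.05 in edgeR; the cause was not tested. The Y-linked covariate gave 0 (0 higher, 0 lower, 0 over 2-fold; 2433 unadjusted), leaving out the crystallin-rich pair 0 (0 higher, 0 lower, 0 over 2-fold; 1306 unadjusted), and leaving out the multiply aligned pair 41 (25 higher, 16 lower, 36 over 2-fold). These fits hold fewer libraries or residual degrees of freedom, and the cause was otherwise not tested. No scaling moved the median of all genes by over 0.1. Without 1 library the log2 fold change of Mycn ran from -0.17 to 0.31, reversed only without Rb-null 3, and that of Rb1 from -0.14 to 0.036, reversed without TET-MYCN 4 (0.036) and Rb-null 1 (0.014), with none past the threshold in edgeR. Lists called by camera were 18 to 21 without 1 library, 18 with other scaling or filter, 19 without either pair of libraries, and 0 with an estimated correlation and 0 with fry, which measure the spread between libraries. Exact permutation gave 0, but could pass a list only if 19 of the 32 had its smallest p. A count of 3 in a library is 0.131 to 0.202 CPM, which limits genes such as Mmp12 in the Rb-null libraries.

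Library numbers are shared by the groups, but correlations of deviations for the same number were -0.0402, -0.0619, -0.122 and -0.295. These values give no sign that the numbers pair the libraries, though they cannot exclude a shared batch. With the replicate block edgeR called 3 genes (3 higher, 0 lower, 3 over 2-fold), all among the 9, and camera 18 lists.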

Other observations

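The genes in the next 2 paragraphs were chosen after their values were seen, and the grouping of the libraries' correlations was also seen first. Spp1, the secreted phosphoprotein osteopontin, was 5.41 ± 1.39 CPM in the Rb-null libraries and 265, 18.7, 105 and 402 CPM in TET-MYCN 1 to 4 (log2 fold change 5.19 ± 0.81, adjusted p = 0.0641 in edgeR). Gpnmb, a lysosomal glycoprotein gene, was 4.84 ± 0.140 CPM and then 82.8, 13.0, 27.4 and 121 CPM (3.65 ± 0.62, adjusted p = 0.0858). Lgals3, which codes for galectin-3, was 6.84 ± 0.578 CPM and then 20.3, 7.79, 19.7 and 26.6 CPM (1.44 ± 0.31, adjusted p = 0.155). Of the 23 microglia and macrophage genes 17 were positive, with a median log2 fold change of 0.14 and a mean of 0.45 (adjusted p = 0.103, camera; adjusted p = 0.805 with an estimated correlation). The list's mean log2 CPM was 3.78, 4.16, 3.32 and 3.85 in Rb-null 1 to 4. In TET-MYCN 1 to 4 it was 4.00, 3.52, 4.44 and 4.66, so it was highest in TET-MYCN 3 and 4. TET-MYCN 2 lay below Rb-null 1, 2 and 4. The matrix genes Has2, a hyaluronan synthase, Vcan and Fbln1 had log2 fold changes of 4.33 ± 0.63, 1.84 ± 0.40 and 2.37 ± 0.46 (adjusted p = 0.0569, 0.155 and 0.132). None of these genes passed the threshold in edgeR over all genes, while DESeq2 called Spp1, Gpnmb, Lgals3, Has2, Vcan and Fbln1 and also, as higher, the macrophage-expressed genes Mrc1, Msr1, Ms4a7, Itgax and Cybb, and Spp1 and Lgals3 are the microglia and macrophage genes that passed adjusted over the list alone.

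Onecut2 was 126, 47.7, 20.7 and 70.9 CPM in TET-MYCN 1 to 4 and 23.3 ± 6.50 CPM in the Rb-null libraries (1.51 ± 0.46, adjusted p = 0.194), and Onecut1 was 29.9, 14.2, 1.24 and 23.5 CPM against 6.53 ± 2.27 CPM (adjusted p = 0.348). Dlx1 was 24.5, 5.37, 3.04 and 32.5 CPM against 1.51 ± 1.32 CPM (3.42 ± 0.82, adjusted p = 0.158), and Barhl1 was 39.4, 5.02, 2.70 and 37.4 CPM against 1.43 ± 0.622 CPM (3.86 ± 0.86, adjusted p = 0.155). Among lower values, Lynx1, which codes for a modulator of nicotinic receptors, had -1.67 ± 0.25, Lhx4, a bipolar cell transcription factor, -1.08 ± 0.20, and the circadian genes Per3 and Bhlhe41 -0.61 ± 0.10 and -0.85 ± 0.13 (adjusted p = 0.0569, 0.111, 0.0712 and 0.0641). These genes did not pass the threshold in edgeR, while DESeq2 called Dlx1, Barhl1, Lynx1, Lhx4, Per3 and Bhlhe41.

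Rb-null 4 and TET-MYCN 3 had the highest correlation of deviations from their group means between groups, 0.448 across genes, which are not independent replicates. They also had the closest pair of Xist levels among libraries holding both kinds of reads, at 584 and 503 CPM, with Y-linked sums of 157 and 149 CPM.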
